A study of Saccharomyces bayanus x Saccharomyces cerevisiae with 8 samples.

How the data were processed

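Allele-specific RNA sequencing was analysed in OZY27, a diploid hybrid yeast that carries 1 genome of Saccharomyces cerevisiae, isogenic to the laboratory strain W303, and 1 genome of Saccharomyces bayanus. Per the labels' protocols, 2 separate cultures were grown to log phase in the rich glucose medium YPD, total RNA was extracted with hot acid phenol and treated with DNase, and 1 Illumina library was made from each culture. The 8 samples are sequencing lanes of these 2 libraries. Biological replicate 1 was run in lanes 1, 2 and 5 at UCB and in lanes 6 and 8 at UCR, and biological replicate 2 in lanes 3 and 4 at UCB and in lane 7 at UCR.

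The authors deposited raw counts of reads per gene, lane and allele for 4238 pairs of orthologs, each named by the systematic ORF name of the S. cerevisiae gene. Bowtie was used for mapping, per the submitters' processing notes; its version and settings, the genome builds, the annotation and the rule for reads that map to both genomes are not given in the sources used here. The deposited table also gives, for each ortholog, its length and the number of its bases in which reads can be mapped. Its natural log ratios of S. bayanus to S. cerevisiae reads were computed by the authors for each biological replicate, with a started value that the sources used here do not give. The authors also deposited a resampling p-value for each biological replicate and a score of -1, 0 or 1 that combines the signs and both p-values into 1 call per gene. The GC difference of the orthologs is deposited as a fraction, S. bayanus minus S. cerevisiae, and is given here in percentage points. Another 4 deposited columns, sums over the lanes of each biological replicate and allele, were not used here. The authors' column description gives some of these columns another replicate number and calls the GC difference a percentage; the numbering of the lanes and the range of the values were followed instead. Strand was not used.

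Lanes of a library are repeat runs and not replicates, so their counts were summed and n = 2. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on 4 columns of summed counts (2 biological replicates by 2 alleles), with the biological replicate as a block, since both alleles are read in the same library. Each allele column was scaled by its own total with TMM factors, which sets the typical gene to an allele ratio near 1, and the log of the mappable length entered as an offset for each gene and allele. Genes needed at least 10 reads over both alleles in each biological replicate; 4197 genes met this and 41 did not. A gene is said to differ when its p adjusted by Benjamini-Hochberg is under 0.05. Log2 ratios are S. bayanus minus S. cerevisiae, so positive values mark a higher S. bayanus allele. The ratio between sequencing sites was tested as an allele by site interaction on sums per replicate and site. The ratio between the cultures was tested as an allele by replicate interaction with the 16 lane columns as units. Its p-values measure the spread between lanes of a library only, because each culture gave 1 library. DESeq2 1.42.0 was run as well, and descriptive tests were computed in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. Chromosome medians were compared with 10000 random gene sets of the same size, and permutation tests across genes used 10000 permutations and were two-sided, with 2000 for the adjacent ORFs under alternative settings and 500 for windows of ORFs.

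Every lane held between 2350222 and 3159446 counted reads. Intervals of shares are exact binomial intervals at 95% and cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules. On simulated data with the means and depths of the 4197 genes, the allele test recovered 0% of genes changed 1.2-fold, 70% of those changed 1.5-fold and 98% of those changed 2-fold, with 6 false calls. Only 50 genes were changed at each fold, far fewer than differed in the real data. The adjusted threshold was therefore stricter in the simulation, and its recovery of small changes does not carry over to the real data. The culture test recovered 42%, 76% and 98% with 2 false calls, and the site test 28%, 76% and 92% with 6 false calls. For both of these tests the allele ratios of simulated lanes varied by counting error only, and the site simulation held no culture difference. Real lanes of a library varied by more than counting error, so recovery may be lower and false calls more frequent in the real data. Genes that share reads with a close paralog or an overlapping ORF are uncertain.

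The design, the filter, the scaling, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were other scalings, filters and tests, a fit without the replicate block, lanes as units, each site alone, each lane or replicate left out, and a fit without the length offset. A correction for the GC difference (a lowess of span 0.5 of the log2 ratio), a restriction to genes whose mappable lengths differ by less than 5%, a culture term in the site test, and all alternatives of the culture test and of the chromosome medians were chosen after seeing the data. The rule for named genes was the 12 largest ratios toward each allele among genes that differed, had the same direction in both replicates and at both sites, and had at least 10 reads from the lower allele in each replicate. The files pair no systematic name with a gene symbol or function, so at most 2 systematic names per direction are given for each comparison. For the same reason the gene lists fixed beforehand (biosynthetic pathways, stress, mating, cell wall, ribosome and others), the auxotrophic marker genes of the strain and the most abundant genes of the rule are not analysed here. Chromosome, arm, order and strand were read from the systematic names and refer to the S. cerevisiae genome. No reference sequence was used here, so no coordinates are given.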

Results

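Expression of the 2 alleles of each gene was measured in a hybrid of S. cerevisiae and S. bayanus, in which both genomes share 1 nucleus and 1 medium, so that a difference between the alleles of a gene arises within the same cells. In all, 22930124 reads were assigned to an allele, 14707025 in biological replicate 1 (5 lanes) and 8223099 in biological replicate 2 (3 lanes). The median gene had 1710 reads over both alleles in replicate 1 and 899 in replicate 2, and no gene took more than 0.615% of all reads. Lanes of a culture differed from each other by more than counting error and by less than lanes of different cultures, with a median chi-square per degree of freedom of 1.93 for 5 pairs of lanes run at 1 site and 2.14 for 8 pairs run at different sites. Lanes of different cultures had medians of 15.8 and 17.7.

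The genomes contributed nearly equal numbers of reads. The S. cerevisiae alleles held 48.8% of the reads in replicate 1 and 47.3% in replicate 2, a mean of 48.1% ± 1.04 (SD, n = 2). Single lanes ranged from 46.6% (46.6 to 46.7, exact binomial interval) in lane 4 of replicate 2 to 49.4% (49.3 to 49.5) in lane 1 of replicate 1. The lanes of replicate 1 lay between 48.3% and 49.4% and those of replicate 2 between 46.6% and 48.2%.

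The design asks which orthologs are expressed unequally in the hybrid. The alleles differed in 2246 of 4197 genes (53.5%), with the S. bayanus allele higher in 1117 and the S. cerevisiae allele higher in 1129. Most differences were under 2-fold. The ratio was at least 1.5-fold in 1244 of these genes (604 toward S. bayanus, 640 toward S. cerevisiae), at least 2-fold in 555 (275 and 280), at least 4-fold in 142 (65 and 77) and at least 8-fold in 48 (26 and 22). The median absolute log2 ratio was 0.37 (1.30-fold) over all tested genes and 0.64 (1.56-fold) over the genes that differed, with a median standard error of 0.11. All 2246 genes had the same direction in both replicates and at both sites. This agreement is no separate evidence, because the test rarely calls a gene whose replicates disagree, and both sites read the same libraries. Over all 4197 tested genes, 3603 (85.8%) had the same direction in both replicates and 3851 (91.8%) at both sites. Across genes, which are not independent replicates, the log2 ratios of the replicates had a Pearson correlation of 0.905 and a Spearman correlation of 0.873.

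**Figure D1:**
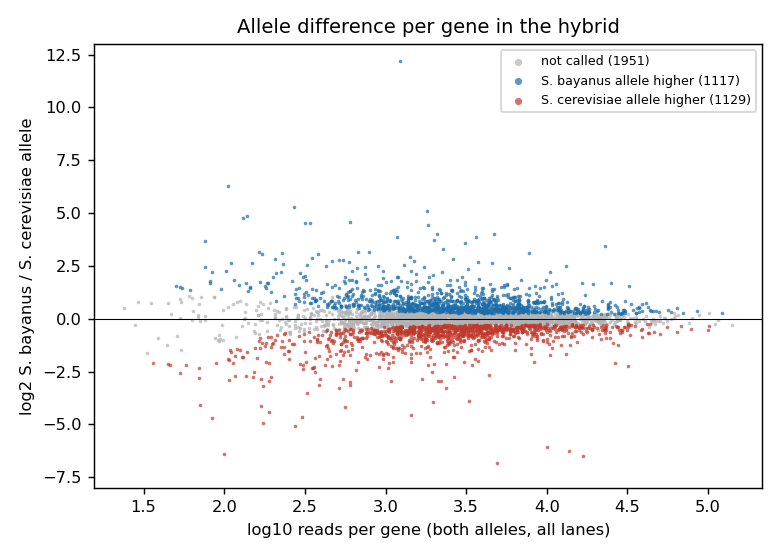
Log2 ratio of S. bayanus to S. cerevisiae expression of each gene, against log10 of its reads over both alleles and all lanes. Blue points are the 1117 genes with a higher S. bayanus allele, red points the 1129 with a higher S. cerevisiae allele and grey points the 1951 others; the ratios spread most widely at low read numbers.

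The 12 genes named toward S. cerevisiae had ratios of 7.89-fold to 112-fold, and the 12 toward S. bayanus 8.82-fold to 34.3-fold. The auxotrophic marker genes of the strain were not identified or removed, so some of these ratios may belong to altered marker genes. The largest ratio toward S. cerevisiae was that of YDR033W, on the right arm of chromosome IV, at a log2 ratio of -6.81 with a standard error of 0.14 (edgeR, adjusted p = 0.00010). Its S. cerevisiae allele had 445 ± 19.2 CPM (reads scaled to the total of that genome) and its S. bayanus allele 3.91 ± 0.299 (SD, n = 2), from 3098 and 1786 reads against 31 and 16 in replicates 1 and 2. YGR234W, on the right arm of chromosome VII, had a log2 ratio of -6.51 with a standard error of 0.26 (edgeR, adjusted p = 0.000245), at 1491 ± 22.8 CPM for the S. cerevisiae allele and 16.3 ± 8.34 for the S. bayanus allele. Toward S. bayanus, YPL171C on the left arm of chromosome XVI led the genes with at least 10 reads from the lower allele in each replicate, at 5.10 with a standard error of 0.26 (edgeR, adjusted p = 0.000388). Its S. bayanus allele had 167 ± 102 CPM and its S. cerevisiae allele 4.20 ± 0.231, and its S. bayanus ortholog is 10.4 percentage points richer in GC. YJL045W, on the left arm of chromosome X, followed at 4.59 with a standard error of 0.23 (edgeR, adjusted p = 0.00033), at 49.1 ± 2.14 against 2.12 ± 0.634 CPM. Its S. cerevisiae allele had only 12 and 10 reads in replicates 1 and 2, at the minimum of 10 for a named gene. All 4 genes had the same direction in 8 of 8 lanes.

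Large ratios were more frequent among weakly expressed genes. Ratios of at least 2-fold that passed the test made up 30.8% of the 842 genes in the lowest quintile of read number and 12.8%, 9.77%, 7.39% and 5.36% of the following quintiles. The share of genes that differed at any size changed little, from 56.1% in the lowest quintile to 50.4% in the highest. Of the 2246 genes, 64 had fewer than 10 reads from the lower allele in a replicate, and the size of their ratio is less certain.

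The near balance between the directions follows from scaling each genome to its own total. With 1 library size for both alleles of a replicate, which leaves the ratio uncentred and shifts the median gene by 0.11 toward S. bayanus on the log2 scale, 2132 genes differed, 1319 toward S. bayanus and 813 toward S. cerevisiae. The authors' deposited table holds 2074 calls, 1233 toward S. bayanus and 841 toward S. cerevisiae. Of the genes tested here, 1900 had the same direction in the authors' deposited table and in the edgeR test and 0 had opposite directions. Only the authors' deposited table called 169 genes toward S. bayanus and 2 toward S. cerevisiae, and only the edgeR test called 55 toward S. bayanus and 291 toward S. cerevisiae. Without the replicate block, 866 genes differed, and DESeq2 called 1480.

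Genes whose S. bayanus ortholog was richer in GC tended to have a higher ratio of S. bayanus to S. cerevisiae reads. The median log2 ratio was -0.20 in the quintile of genes with the lowest GC difference (S. bayanus minus S. cerevisiae), -0.09, 0.01 and 0.14 in the next quintiles, and 0.19 in the highest. In the lowest quintile 126 genes differed toward S. bayanus and 325 toward S. cerevisiae, and in the highest quintile 321 and 149. Spearman's rho across the 4197 genes, which are not independent, was 0.249 (permutation p = 0.0001, the smallest that the permutations can give). The replicates differed in shape at the upper end. In deciles 8 and 9 of the GC difference the median log2 ratio was 0.19 and 0.13 in replicate 1, and 0.19 and 0.17 in replicate 2. In the decile of genes with the highest GC difference, the median log2 ratio was 0.09 in replicate 1 and 0.45 in replicate 2. The rise therefore did not continue past decile 8 in replicate 1.

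**Figure D2:**
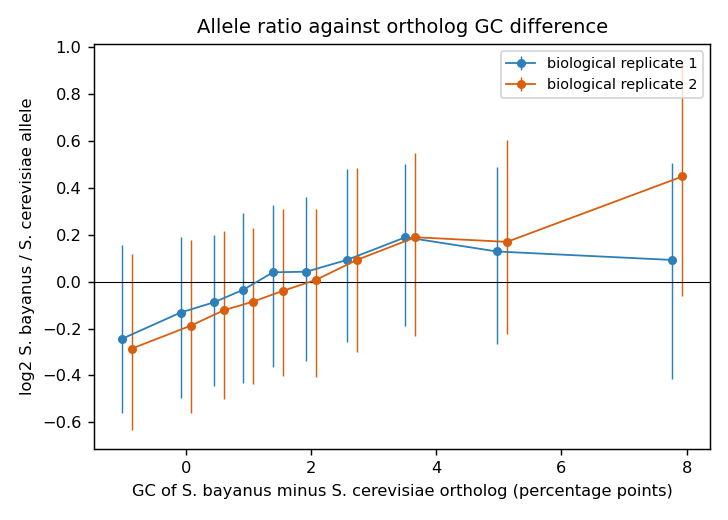
Median log2 ratio of S. bayanus to S. cerevisiae expression in deciles of genes ordered by the GC difference of the orthologs in percentage points, for each biological replicate; bars span the quartiles of the genes, and the replicates are drawn slightly apart along the horizontal axis. The replicates run close together except in the last decile, at 0.09 and 0.45.

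No chromosome stood apart in its allele ratio, the question raised by a possible gain or loss of a chromosome in the hybrid. Chromosome medians ran from -0.06 on XI to 0.08 on XV, where an extra copy of 1 allele would give a shift of 1 on the log2 scale. A S. bayanus chromosome that is rearranged relative to S. cerevisiae would spread such a shift over parts of several of these chromosomes. Against random gene sets of the same size, 0 of 16 chromosomes had an adjusted p under 0.05, and the smallest was 0.302 (permutation, Benjamini-Hochberg), for XV. After GC correction the medians ran from -0.12 on IX to 0.08 on II, again with 0 chromosomes at an adjusted p under 0.05 (smallest 0.168, permutation), for IX. Before this correction, the medians of the 32 chromosome arms ran from -0.15 (right arm of IX, 28 genes) to 0.20 (left arm of VI, 38 genes).

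**Figure D3:**
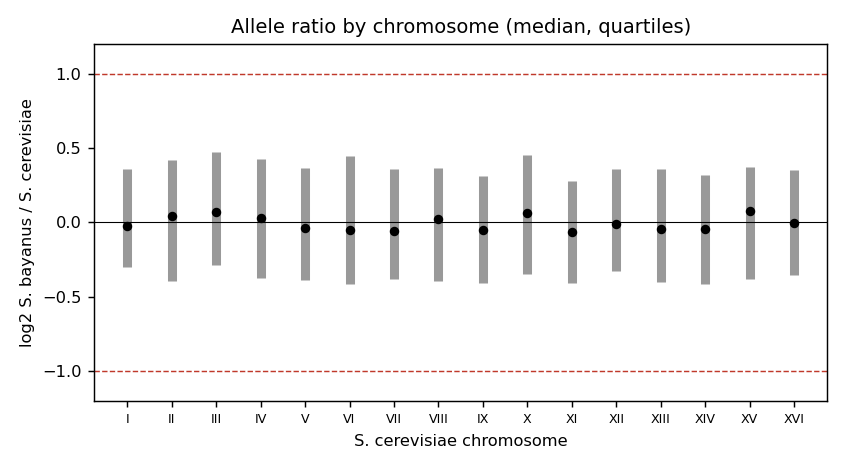
Median and quartiles of the log2 ratio of S. bayanus to S. cerevisiae expression of the genes on each S. cerevisiae chromosome. Dashed lines mark the shift of 1 that an additional copy of either allele would give; the medians lie between -0.06 and 0.08.

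The place of sequencing, a technical batch, made no detectable difference to the ratio of any gene. The edgeR interaction test called 0 genes, with 23 at an unadjusted p under 0.05, and with lanes as units it called 0, with 123 at an unadjusted p under 0.05. These fits leave the difference between the cultures in the error. With a term for it, 0 genes were called and 221 had an unadjusted p under 0.05. The simulation did not cover the fit with this term, so its recovery of changed genes is not known. The log2 ratios from UCB and UCR had a Pearson correlation of 0.962 and a Spearman correlation of 0.955 across genes. Differences between runs did not simply follow the site. Lane 5, run at UCB, had a chi-square per degree of freedom of 1.33 against each of the UCR lanes 6 and 8. Against the UCB lanes 1 and 2 it had 1.93 and 2.34. The site test therefore does not cover all differences between runs.

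The allele ratio differed between the cultures in 752 genes, beyond the spread between lanes of a library (edgeR interaction test). The share of the S. bayanus allele was higher in replicate 2 in 366 genes and higher in replicate 1 in 386. The split depended on processing. It was 414 and 323 with edgeR's RLE size factors in place of TMM, and 447 and 270 with at least 50 reads. After a GC correction in each lane it was 291 and 456. Shifts of at least 2-fold were found in 74 genes, 56 with a higher S. bayanus share in replicate 2 and 18 in replicate 1, and the S. bayanus allele moved more than the S. cerevisiae allele in 63 of the 74. After removal of the GC trend in each lane, 38 genes shifted at least 2-fold, 21 with a higher S. bayanus share in replicate 2 and 17 in replicate 1. The ratio changed sign in 225 of the 752 genes, and in 10 it was at least 1.5-fold in each direction. With the UCB lanes alone 408 genes differed, and each culture gave 1 library, so culture and library cannot be separated.

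Among the 10 genes with a sign change of that size, names were chosen after the values were seen. YML102W, on the left arm of chromosome XIII, had a log2 ratio of -1.61 in replicate 1 and 0.61 in replicate 2, a fitted shift of 2.19 with a standard error of 0.12 (edgeR, adjusted p = 6.22e-15). Its S. bayanus allele rose 5.49-fold between the cultures and its S. cerevisiae allele 1.19-fold. YBR231C, on the right arm of chromosome II, moved from -0.90 to 1.19 (edgeR, adjusted p = 5.05e-11). The S. bayanus orthologs of these genes are richer in GC by 15.8 and 17.3 percentage points, and after removal of the GC trend in each lane their shifts were 1.02 and 0.71. YGR249W, on the right arm of chromosome VII, moved the other way, from 1.55 to -0.71 (edgeR, adjusted p = 0.000415), and had 17 S. bayanus and 24 S. cerevisiae reads in replicate 2. Of the genes named above for their allele difference, YGR234W shifted by -1.06 (edgeR, adjusted p = 0.000219) and YPL171C by 1.23 (edgeR, adjusted p = 0.0401). After removal of the GC trend in each lane, the shift of YPL171C was 0.64 and no longer passed the test (edgeR, adjusted p = 0.349).

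In the quintile of genes with the highest GC difference, 309 genes differed between the cultures, against 98 to 118 in the other quintiles, and the median shift was 0.15 against -0.07 to -0.04. In 47 of the 74 genes with a 2-fold shift, the S. bayanus allele changed at least 2-fold and the S. cerevisiae allele less than 1.5-fold. In 43 of these the S. bayanus allele was higher in replicate 2, and their median GC difference was 10.7 percentage points, against 1.75 over all tested genes.

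**Figure D4:**
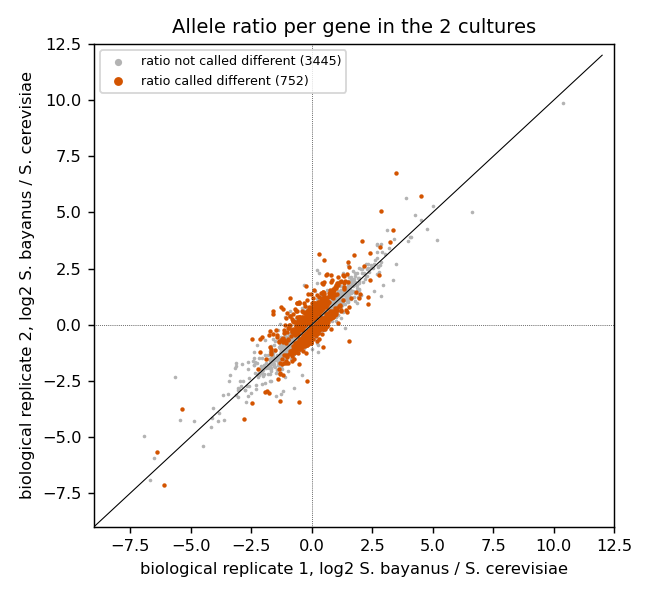
Log2 ratio of S. bayanus to S. cerevisiae expression of each gene in biological replicate 2 against replicate 1, with the line of equal values. Orange points are the 752 genes whose ratio differed between the cultures beyond the spread between lanes, and grey points the 3445 others.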

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

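The tests of other lane splits, of the GC trend and of windows of ORFs were chosen after the result was seen. The 752 genes above drew attention because the interaction test found their allele ratio to differ between the cultures. Of the 56 splits of the 8 lanes into groups of 3 and 5, 1, the real one, gave as many genes, and the highest other split gave 0. Every other split mixes lanes of both libraries, so this shows that lanes of a library resemble each other and does not separate the cultures from their libraries. A gain or loss of a chromosome copy in 1 culture is argued against by chromosome medians of the shift that reach at most 0.0989 in size. Since a rearranged S. bayanus chromosome would shift only parts of these chromosomes, windows of 10 neighbouring ORFs were compared too, and their median shift reached at most 0.51, where a full copy would give 1. The 752 genes had a median of 5569 reads against 2673 in all tested genes, which decides nothing about low counts, since a count test finds more where reads are many. A trend shared by all genes of like GC difference of whole orthologs, and different between the libraries, is argued against as the whole cause. After this trend was removed in each lane, 565 of the 752 genes differed in the same direction. Outside the quintile with the highest GC difference, 98 to 118 genes per quintile differed at median shifts of only -0.07 to -0.04. Removal of the trend could take away few of those calls, so the test was a weak one. A GC bias within parts of a gene would not be removed this way and was not tested. A bias that follows the GC difference remains a candidate explanation for the excess of 2-fold shifts toward replicate 2. The ratio of these shifts to those toward replicate 1 went from 3.11 to 1.24. A difference in growth state between the cultures stays open. By the rule set beforehand, a larger change of total reads in the 752 genes counts for it, and this was met. The rule was set aside after the result was seen, because it cannot separate growth state from the selection of the genes. The 752 genes had a median absolute log2 change of total reads of 0.296, against 0.235 in other genes (permutation p = 0.0001). They were selected by a change of 1 allele against the other, which raises the change of the total by itself. The allele that moved less changed by a median of 0.172, against 0.140 in other genes (permutation p = 0.0001). Both alleles moved in the same direction in 60.1% of the 752 genes, against 76.8% of the others. With 1 library per culture, growth state and library preparation were not separated.

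The rise of the allele ratio with the GC difference of the orthologs is a further pattern; its test by removal of the trend was chosen after the result was seen. Unequal mappable length is argued against, because Spearman's rho was 0.261 among the 3864 genes whose mappable lengths differ by less than 5%. A bias that follows the GC difference of whole orthologs is argued against as the whole cause of the allele differences. After its trend was removed, 1869 of the 2246 genes differed in the same direction. The trend was small, so its removal could take away few calls, and a GC bias within parts of a gene would remain. Such a bias was not tested. A GC bias that differs between runs may still account for part of the trend. The slope of the log2 ratio per GC point ranged from 0.0153 to 0.0419 over the 5 lanes of replicate 1, a range of 0.869 times its mean. Over the 3 lanes of replicate 2 it ranged from 0.0610 to 0.101, a range of 0.499 times its mean. The limit set beforehand lay between these ratios, so only replicate 1 passed it. A true relation between GC content and expression was not tested.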

How the results depend on the processing

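The alternatives for the GC difference, mappable lengths, chromosomes and cultures, and the culture term in the site test, were chosen after seeing the data. The number of genes with an allele difference, 2246, stayed within 1.5 times under 21 alternatives. With each lane left out it was 2038 to 2381. The highest number was 3173, with lanes as units, which counts runs of a library as replicates. The number fell to 866 with no replicate block, to 609 with glmTreat against 1.5-fold and to 1480 with DESeq2. Membership moved more: 1919 of the 2246 genes were also called with 1 library size for both alleles, and 1869 after GC correction. The 1.5-fold number, 1244, stayed within 1.5 times under 23 alternatives and was 609 with glmTreat, which tests against that fold by construction. The pairing rests on both alleles being read in the same library; without it differences between cultures enter the error, and for DESeq2 the cause was not tested. No gene called by both reversed direction in any alternative of the allele test. The culture number, 752, fell to 408 with the UCB lanes alone, which use 5 of 8 lanes, and was 585 to 661 with each lane left out. The largest chromosome median deviation went from 0.08 to 0.14 after GC correction, and the cause was not tested. The log2 ratios of YDR033W (-7.05 to -6.65), YGR234W (-7.13 to -6.10), YPL171C (4.51 to 5.74) and YJL045W (4.24 to 4.77) kept their direction under all 26 alternatives. Leaving out a biological replicate leaves 1 column per allele, so it gives values and no test. Set tests of gene lists were not run because the files do not pair systematic names with gene symbols. In simulated data of this depth the allele test found 0% of genes changed 1.2-fold. Far fewer genes were changed there than differed in the real data, which made the adjusted threshold stricter. In the real data, 1002 of the 2246 genes had ratios under 1.5-fold.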

Other observations

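All tests in this part were chosen after the data were seen, except that the comparisons by orientation of adjacent ORFs were fixed before their result. Between the cultures, the changes of both alleles of a gene were correlated. Over the 3748 genes with at least 200 reads in both cultures, the log2 changes of the S. bayanus and S. cerevisiae alleles had a Pearson correlation of 0.664 across genes, with standard deviations of 0.427 and 0.344. Total expression differed at least 2-fold in 48 genes, 42 higher in replicate 2 and 6 in replicate 1. The S. bayanus allele passed 2-fold more often, in 105 genes against 25 for the S. cerevisiae allele; 9 genes are in both counts. Of the 105 genes, the 85 with a higher S. bayanus allele in replicate 2 had a median GC difference of 9.49 percentage points, and the other 20 of 1.70, against 1.75 over all tested genes. These are values of 2 libraries with no test between cultures.

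In the outermost 10% of ORFs of each arm, 68 of 416 genes (16.3%) had a 2-fold ratio that passed the test, against 476 of 3733 other genes (12.8%; Fisher's exact test, two-sided, p = 0.0461, not adjusted). The outer genes had fewer reads, a median of 2422 against 2713, and large ratios were more frequent at low read numbers. No window of 10 neighbouring ORFs had a median allele ratio beyond those of shuffled genes (largest 0.78, permutation p = 0.735), and the largest window of the culture shift, 0.51 on the left arm of chromosome III, had a permutation p of 0.0958.

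Allele ratios of adjacent ORFs were weakly related in divergently transcribed pairs, but not past the test after GC correction. Spearman's rho was 0.098 over 762 divergent pairs (permutation p = 0.0069, adjusted p = 0.0483 over 7 relations), against 0.019 over 853 convergent and 0.008 over 1409 tandem pairs, while Pearson's r of divergent pairs was 0.000252. After GC correction rho of the divergent pairs was 0.060 and did not pass the test (permutation p = 0.092, adjusted p = 0.644). The hypothesis that a shared promoter region links divergent ORFs was tested by the difference of divergent from other pairs, 0.0861 (permutation p = 0.0397, adjusted p = 0.139). The unadjusted p meets the threshold set beforehand; a demand that the adjusted p meet it too was added after the result was seen, and after GC correction the difference was 0.0551 (permutation p = 0.197), so the hypothesis stays open. Reads shared between overlapping convergent transcripts might raise the correlation of convergent pairs, whose difference from other pairs was -0.0205 (permutation p = 0.61). By the rule set beforehand, a value not above that of other pairs counts against this explanation. The difference is within the spread of permuted orientations, so the explanation is not decided. The culture shift was correlated between adjacent ORFs, at a rho of 0.103 over 3024 pairs (permutation p = 0.0001, the smallest possible). Convergent pairs had a rho of 0.111, tandem pairs of 0.109 and divergent pairs of 0.075 (permutation p = 0.037, adjusted p = 0.0648). The difference of divergent from other pairs was not detectable (-0.038, permutation p = 0.356, adjusted p = 0.499). The culture shift itself rose with the GC difference of the orthologs (Spearman's rho 0.231). Adjacent pairs were not compared for the culture shift after GC correction, so a shared GC difference of neighbours stays open.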
